A study of Homo sapiens with 38 samples.

How the data were processed

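The series holds 38 arrays of RNA from the apex of the left ventricle of 19 patients, each sampled when a left ventricular assist device (a mechanical pump) was implanted and again when it was explanted. Per the labels, total RNA was hybridised to Affymetrix HG-U133A arrays, which measure a transcript with a probe set of short oligonucleotides. The deposited values are 1 intensity per probe set and array on a linear scale, from 0 to 12894.8. The software that computed them and any scaling between arrays are not given in the sources used here. The median deposited intensity of an array lay between 21.3 and 128.1, a gap of 1.95 between the lowest and highest median after log2(value + 16). Intensities of this kind have no counting depth, so the number of arrays limits the precision. All 38 columns were tied to samples by their labels.

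The labels named 3 etiologies: ischemic disease with coronary artery disease (5 patients), a myocardial infarction within 10 days of implant (6 patients, called acute infarction here) and nonischemic disease without coronary artery disease (8 patients). The labels state that the arrays of a patient are paired, so the patient number was the block of every comparison of explant with implant. Deviations of a patient's 2 arrays from their group means correlated with a median of 0.263 (range -0.151 to 0.597), against a median of -0.0499 for arrays of different patients of 1 etiology. The correlation was over 0.1 in 15 of 19 pairs, and 12 of the 19 matched best with their own number. The highest correlation of any 2 arrays was 0.968 and 0 pairs of arrays held identical values. A check for mixed-up samples found 1 patient whose 2 arrays did not match each other. That pair was kept. Leaving out each pair in turn covers its omission for the counts of called genes and the mean changes of the gene lists alone, not for the list tests, the RNA ratios or the tests of the closing section.

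The following choices were made before the data were examined: groups, tests, gene lists, thresholds, the rule for named genes and most of the alternatives. Values were put on log2(value + 16), so changes of dim genes are understated. Because the array medians differed by more than 0.5, the preset rule called for quantile normalization. Of 22283 probe sets, 19065 had 1 gene symbol in the platform table, 1043 had several, 2107 had none and 68 were Affymetrix controls. Symbols were updated through RefSeq for GRCh38.p14, which matched 19053 of the single-symbol probe sets and left 12 under the symbol of the platform table. Control probe sets and 31 probe sets of sex-linked genes were left out of the tests. Each of 11939 genes was represented by its probe set with the highest mean (4304 genes had several), and the lowest 30 percent of genes by mean were left out. That filter removed genes with a mean log2 value below 5.56 and left 8357 genes. Genomic positions were not used here.

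The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), with Benjamini-Hochberg adjustment and a threshold of 0.05. Explant was compared with implant over all 19 pairs, and within each etiology in 1 fit of all pairs that shared an estimate of the spread. Differences of the change between etiologies were tested with a moderated F-test and pairwise contrasts of the same fit. Etiologies were compared at implant and at explant over 19 arrays each. Of 51 gene lists fixed in advance, 47 had at least 5 measured members and 4 did not. They were tested with camera at its preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Camera compares a list with the other genes, and fry asks whether the genes of a list move on balance in 1 direction. The change of a list within an etiology was also tested by exact sign flips of the pairs, and over 19 pairs by 100000 random sign flips, both two-sided. Differences of list means between etiologies were tested by permuting etiologies among patients. RNA integrity was followed by the log2 ratio of the 3' to the 5' or middle control probe sets of GAPDH and ACTB.

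Genes were named by a fixed rule. The named genes were the 10 largest rises and 10 largest falls past the threshold and in the same direction in at least 15 of 19 pairs; GATA4 and SPRY1, which the labels give as keywords; up to 3 called members of each list, or the 2 brightest members where none was called; and the 5 largest called changes per etiology contrast, or the 3 smallest p-values where none was called. List members past a threshold over the list alone are also named and were chosen after their values were seen.

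The pipeline was tested on simulated data with the spread of the 8357 genes and 200 genes changed by known sizes. Over all pairs it recovered 59.2 percent of changes of 0.5 and 95.6 percent of changes of 1 on the log2 scale, with 5.46 percent false calls. At a change of 1 it recovered 56.8 percent in ischemic, 69.2 percent in acute infarction and 81.2 percent in nonischemic pairs. For a difference of 1 in change between etiologies recovery was 46.8 percent, and for a difference of 1 at implant 69.2 percent. The simulated noise was independent between genes and had the same spread in every group. Recovery within etiologies therefore differs through the number of pairs alone. Arrays that stand apart, a wider spread in 1 etiology and genes that move together were not simulated, so recovery in the real pairs may differ. The alternatives covered the filter, normalization, pseudocount, choice of probe set, moderation, array weights, patient block, an RNA integrity covariate and the omission of each pair. Further alternatives were chosen after seeing the data: omission of the 2 acute infarction pairs with the arrays of lowest correlation to the rest, covariates for array brightness and cardiomyocyte markers, sign flips of list changes, other scalings for the lists, omission of each pair in the test between etiologies and for the mean changes of the lists, and omission of 2 nonischemic explant arrays from the list levels at explant. Figures were drawn with Python 3.11.15.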

Results

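Left ventricular apex tissue was profiled at implant and at explant of a left ventricular assist device, which takes over part of the pumping work of the failing heart. The 38 arrays came from 5 patients with ischemic disease, 6 with an acute infarction shortly before implant and 8 with nonischemic disease. The cardiomyocyte genes MYL2, the ventricular regulatory myosin light chain, and MB (myoglobin) had mean log2 intensities of 12.5 and 12.2. The mean of the cardiomyocyte markers was 11.4 ± 0.56 (SD, n = 5) in ischemic, 10.4 ± 2.45 (n = 6) in acute infarction and 11.6 ± 0.17 (n = 8) in nonischemic tissue at implant. At explant the corresponding means were 11.7 ± 0.02, 11.8 ± 0.15 and 11.4 ± 0.27. Macrophage marker means at implant were 7.04 ± 0.85, 8.14 ± 1.54 and 7.29 ± 0.81 in the same order. A single acute infarction array at implant, that of pair 3, stood apart with a mean correlation of 0.565 to the others, where MYL2 was 5.29 and the macrophage scavenger receptor CD163 was 11.96. Median deposited intensities ranged from 21.3 to 128.1 between arrays, and values were quantile normalized.

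**Figure D1:**
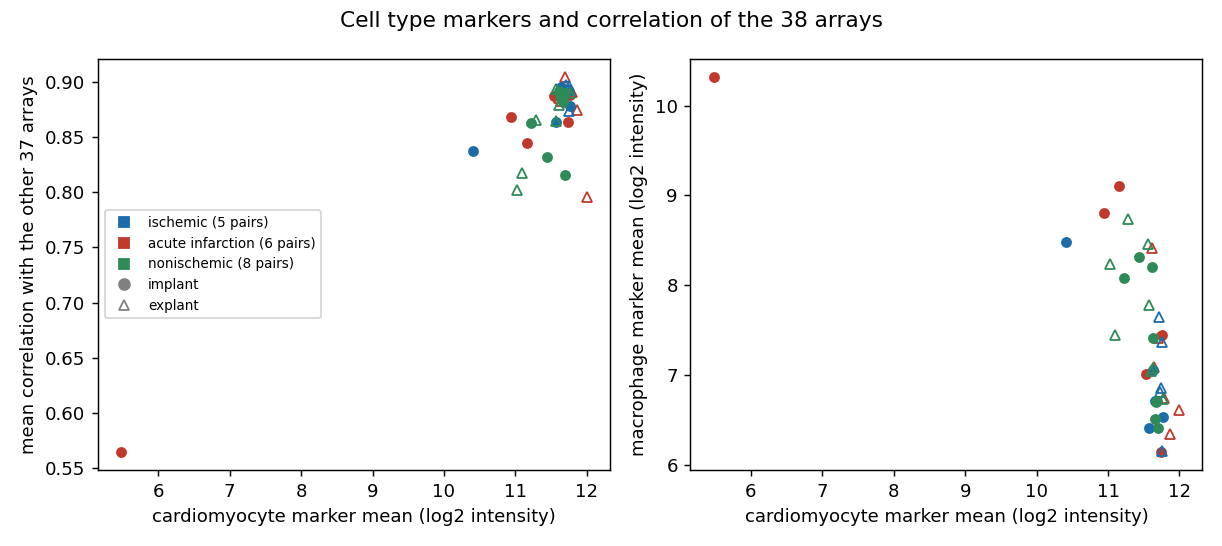
Each point is 1 of the 38 arrays. The x axes give the mean log2 intensity of the cardiomyocyte markers and the y axes the mean correlation with the other 37 arrays (left) and the mean log2 intensity of the macrophage markers (right), with colour for etiology, filled circles for implant and open triangles for explant. The acute infarction implant array of pair 3 lies apart, at a cardiomyocyte mean of 5.48 and a macrophage mean of 10.3.

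The first comparison asked which genes changed between implant and explant across all 19 patients. FKBP5, a co-chaperone of steroid receptors, rose by 1.74 ± 0.35 on the log2 scale (SE, n = 19), a fold of 3.33, and was higher at explant in 15 of 19 pairs. PDK4, the kinase that switches off pyruvate dehydrogenase and so limits glucose oxidation, rose by 1.48 ± 0.28, a fold of 2.79, and was higher in 16 pairs. GADD45G, a stress-induced growth arrest gene, rose by 0.96 ± 0.20, and the transcription factor KLF9 by 0.78 ± 0.16. NRP1, a co-receptor for vascular endothelial growth factor and semaphorins, fell by 0.48 ± 0.08 and was lower in 19 of 19 pairs. With limma, the adjusted p was 0.0244 for NRP1, 0.0425 for PDK4 and KLF9, and 0.0457 for FKBP5 and GADD45G.

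Smaller rises were those of TIPARP, a poly(ADP-ribose) polymerase family member, by 0.78 ± 0.15, the chromatin-binding ATPase ATAD2 by 0.74 ± 0.15, and the translesion DNA polymerase REV1 by 0.60 ± 0.11. NFIL3, a transcriptional repressor linked to the circadian clock, rose by 0.59 ± 0.11. TXNIP, which binds and inhibits thioredoxin, rose by 0.40 ± 0.08 and TOB2, an antiproliferative gene, by 0.35 ± 0.07. ATAD2 was higher in 18 of 19 pairs, TIPARP, REV1, TXNIP and TOB2 in 17, and NFIL3 in 16. COMMD8, of the copper metabolism domain family, fell by 0.47 ± 0.09 and was lower in 17 of 19 pairs. In limma these genes had an adjusted p of 0.0425, or 0.0457 for TXNIP. The probe sets were 204560_at for FKBP5, 205960_at for PDK4, 204121_at for GADD45G, 203542_s_at for KLF9, 212665_at for TIPARP and 212298_at for NRP1. Among 7 further probe sets of 4 called genes, 6 gave the same direction, and 1 dim KLF9 probe set (mean log2 5.23) gave -0.13 ± 0.11. The other TXNIP probe sets rose more, by 0.66 ± 0.12 and 0.80 ± 0.19, and that of TOB2 by 0.59 ± 0.21. Those of NRP1 gave -0.44 ± 0.12 and -0.49 ± 0.13. The sizes for TXNIP and TOB2 thus depend on the probe set.

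Together limma called 12 of 8357 genes, 10 higher and 2 lower at explant. At an unadjusted p under 0.05 there were 610 genes, 304 higher and 306 lower, against 418 from chance alone. Without the patient block 2 genes passed the threshold, GADD45G and WDR62, and with array weights 141 did, 94 higher and 47 lower, among them all 12. Leaving out 1 pair at a time gave between 0 calls (for example without acute infarction pair 5) and 33 (without nonischemic pair 2), and the values as deposited gave 0. FKBP5 was dim at implant (5.37 ± 1.19, SD), and its change was 2.42 with a pseudocount of 1 (adjusted p = 0.116) and 1.09 with 64 (adjusted p = 0.0275).

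SPRY1 and GATA4 are keywords of the study. SPRY1, which encodes an inhibitor of receptor tyrosine kinase and ERK signalling, had a change of 0.45 ± 0.11 and was higher at explant in 16 of 19 pairs, with an adjusted p of 0.110 in limma over all genes. In the fixed list of FGF, Sprouty and ERK feedback genes (17 measured), adjusted over the list alone, SPRY1 (adjusted p = 0.00673) and FGF12 (0.64 ± 0.19, adjusted p = 0.0249) rose and 0 fell. The list as a whole did not rise, with a mean change of -0.03 over all pairs. Without acute infarction pairs 1 and 3 its mean was -0.09 ± 0.04 (SE, n = 17), higher in 5 of 17 pairs (sign-flip permutation p = 0.0320, unadjusted). GATA4, a transcription factor of the cardiac hypertrophic programme, had a change of -0.30 ± 0.18 and was higher at explant in 4 of 19 pairs (adjusted p = 0.788, limma). By etiology the GATA4 change was -0.30 ± 0.33 in ischemic, 0.24 ± 0.30 in acute infarction and -0.70 ± 0.26 in nonischemic pairs, where it was higher in 0 of 8. GATA4 measured 5.28 on the implant array of acute infarction pair 3 that held few cardiomyocyte transcripts, and without that pair the acute infarction mean was -0.16 (n = 5). With array weights both genes passed the threshold, at 0.48 (adjusted p = 0.00363) for SPRY1 and -0.52 (adjusted p = 0.0214) for GATA4.

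**Figure D2:**
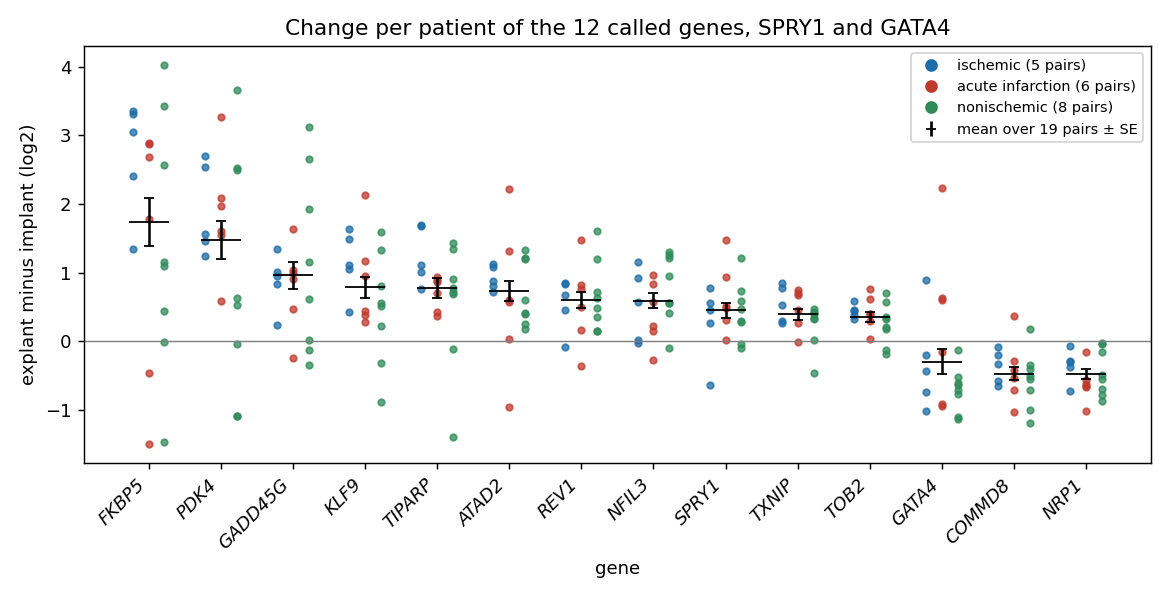
The y axis gives explant minus implant on the log2 scale for the genes on the x axis, with 1 point per patient coloured by etiology and black bars for the mean ± SE over 19 pairs. NRP1 lies below 0 in 19 of 19 pairs and FKBP5 above 0 in 15.

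Gene lists were examined for groups of genes that moved together over all pairs. The metallothioneins, small metal-binding proteins, were the list with the smallest p: its mean change was 0.67 ± 0.18 (SE, n = 19) and it was higher at explant in 16 of 19 pairs. Of its 8 measured members 7 rose adjusted over the list alone, led by MT1M (1.33 ± 0.31), MT1F (0.79 ± 0.23) and MT1E (0.69 ± 0.16), with MT2A at 0.65 ± 0.20. None of the 8 was called over all genes. MT2A and MT1X (0.68 ± 0.22) were measured by probe sets of the cross-hybridizing kind. The estimated correlation between the genes of this list was 0.554, against the 0.01 preset for camera. The 7 rises are thus not 7 independent results, and signal shared between the probe sets was not tested. Of 33 immediate early genes, which respond within minutes to stimulation, 6 rose adjusted over the list alone: NFIL3, RHOB (0.68 ± 0.17), IER5 (0.73 ± 0.21), GADD45B (0.90 ± 0.27), FOSL2 and ATF3. Among 26 growth and IGF signalling genes 4 rose adjusted over the list alone, the transcription factors FOXO3 (0.71 ± 0.16) and FOXO1 (0.38 ± 0.12), PIK3R1 (0.72 ± 0.17) and IRS2 (0.70 ± 0.16). The FOXO factors are held inactive by insulin signalling, whereas IRS2 and PIK3R1 carry its signal.

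Camera with the preset correlation placed 15 of 47 lists past the threshold, 13 higher and 2 lower. The adjusted p was 2.75e-11 for metallothioneins, 4.95e-06 for immediate early genes and 5.78e-04 for growth and IGF signalling; with an estimated correlation 0 lists passed, 2 of them at an unadjusted p under 0.05, and these lists had adjusted p = 0.157, 0.882 and 0.465 with an estimated correlation. Sign flips of the pairs likewise placed 0 lists past the threshold after adjustment, 3 at an unadjusted p under 0.05, with an adjusted permutation p of 0.0855 for metallothioneins, and fry placed 0 (lowest adjusted p 0.0606).

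Muscle and energy genes made up most of the other lists placed higher by camera. All 21 measured sarcomere genes had a positive mean change, with 0 past the threshold adjusted over the list alone, and the list mean was 0.41 ± 0.33 with 10 of 19 pairs higher. TTN, the giant spring protein titin, changed by 0.42 ± 0.30 and MYL2 by 0.37 ± 0.37. The 18 cardiomyocyte markers, all of them also members of another list, had a mean of 0.45 ± 0.33, the 21 calcium handling genes 0.16 ± 0.13, the 67 oxidative phosphorylation genes 0.09 ± 0.11, the 38 fatty acid genes 0.14 ± 0.08 and the 23 TCA cycle genes 0.18 ± 0.15. PDK4 was the 1 member of the fatty acid and TCA cycle lists that rose adjusted over the list alone. Sarcomere genes had adjusted p = 9.12e-06 with camera and adjusted p = 0.882 with an estimated correlation. Without acute infarction pairs 1 and 3 the sarcomere mean was 0.06 ± 0.12 (n = 17), the cardiomyocyte mean 0.09 ± 0.11, the oxidative phosphorylation mean -0.02 ± 0.09, the calcium handling mean 0.03 ± 0.05, the fatty acid mean 0.06 ± 0.05 and the TCA cycle mean 0.03 ± 0.11.

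The lists of ribosomal proteins (mean 0.04 ± 0.04), fibroblast markers (0.19 ± 0.25), smooth muscle and pericyte markers (0.19 ± 0.19) and cytoskeleton genes (0.08 ± 0.06) were also placed higher by camera, and interferon response (-0.10 ± 0.06) and neutrophil markers (-0.40 ± 0.29) lower. The smallest adjusted p among these 6 lists was that of ribosomal proteins, 0.00926 with camera and adjusted p = 0.910 with an estimated correlation. Of the 19 fibroblast markers 12 were also in another list, and of the 16 smooth muscle and pericyte markers 6. The brightest of the latter was CASQ2, with a change of 0.41 ± 0.34. These 2 marker lists therefore do not follow those cell types alone. Among 32 interferon response genes LGALS3BP rose adjusted over the list alone (0.48 ± 0.11), against the direction of the list. S100A8, a calcium-binding protein of neutrophils, had a change of -0.83 ± 0.38. Macrophage markers (-0.18 ± 0.30), endothelial markers (0.02 ± 0.09), T and NK cell markers (0.02 ± 0.09), collagens and matrix (0.09 ± 0.22) and heat shock genes (0.09 ± 0.10) were not placed past the threshold by camera. Without acute infarction pairs 1 and 3 (n = 17) the mean was 0.06 ± 0.07 for smooth muscle and pericyte, 0.14 ± 0.20 for fibroblast and -0.15 ± 0.25 for neutrophil markers, 0.05 ± 0.17 for collagens and matrix and 0.02 ± 0.06 for heat shock genes, and the sign turned for macrophage (0.14 ± 0.23) and endothelial markers (-0.02 ± 0.04). Without pair 3 alone (n = 18) the fibroblast mean was 0.04, the collagen mean -0.04 and the heat shock mean 0.01. Leaving out each pair in turn, chosen after seeing the data, turned the sign of the mean over all pairs in 16 of 47 lists and moved it by more than 1.5 times in 44; the other 3 were metallothioneins (0.58 to 0.77), red blood cell genes (-0.23 to -0.14) and Purkinje and conduction markers (-0.44 to -0.29). The last, 5 measured genes with NPPA among them, had a mean of -0.35 ± 0.15 and were higher in 4 of 19 pairs (permutation p = 0.0330, adjusted permutation p = 0.517), and -0.45 ± 0.13 without acute infarction pairs 1 and 3 (permutation p = 0.00290, unadjusted), where metallothioneins had 0.64 ± 0.19 (permutation p = 0.00437). The Purkinje and conduction mean leans on NPPA, which changed by -1.06 ± 0.41, against -0.15 ± 0.16 for ID2 of the same list. Of its 5 genes 4 were also in another list.

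In the 5 ischemic pairs the smallest p-values belonged to genes already called over all pairs. TIPARP had a change of 1.25 ± 0.28, FKBP5 of 2.69 ± 0.67 and KLF9 of 1.14 ± 0.29, each higher in 5 of 5 pairs and each with an adjusted p of 0.999 in limma. The fatty acid list had a mean of 0.23 ± 0.18 (SD, n = 5) and was higher in 5 of 5 pairs, with an exact sign-flip p of 0.0625, the smallest that 5 pairs can give (0.734 adjusted over 47 lists); without pair 13 the mean was 0.15. Metallothioneins had a mean of 0.67 ± 0.76 and were higher in 4 of 5 pairs, with 0.40 left without pair 7. The limma fit called 0 genes, with 237 at an unadjusted p under 0.05, and camera placed 9 lists past the threshold, 8 higher and 1 lower, with 0 left and a lowest adjusted p = 0.947 with an estimated correlation. Array weights gave 1 call, TIPARP, and a fit of the ischemic pairs alone gave 3: FKBP5, PDK4 and, lower, the secreted phospholipase PLA2G2A (-1.74). Pair 13 had the highest change of the cardiomyocyte markers, 1.30 against at most 0.19 in the other ischemic pairs.

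In the 6 acute infarction pairs the list means of muscle and mitochondrial genes were above 0 and that of macrophage markers was below 0, with a wide spread between patients and none past an exact test adjusted over 47 lists (lowest adjusted p 0.565). The sarcomere mean was 1.31 ± 2.31 (SD, n = 6; higher in 5 of 6 pairs; exact p = 0.0938), the TCA cycle mean 0.64 ± 0.80 (exact p = 0.125), the oxidative phosphorylation mean 0.47 ± 0.58 (exact p = 0.125) and the macrophage mean -1.03 ± 1.76 (exact p = 0.25). Pair 3, whose implant array had a cardiomyocyte mean of 5.48, contributed a sarcomere change of 5.95. Without pairs 1 and 3 the means were 0.29 for sarcomere, 0.22 for the TCA cycle, 0.16 for oxidative phosphorylation and -0.12 for macrophage markers (n = 4), and without pair 3 alone the TCA cycle mean was 0.38. The mean changes of the RNA ratios given below were below 0 in these pairs. The smallest p-values belonged to ETV5, a transcription factor downstream of FGF and ERK signalling (-1.12 ± 0.22, higher in 1 of 6 pairs), the heparin-binding growth factor PTN (1.01 ± 0.20, 6 of 6, but 0.11 without cross-hybridizing probe sets) and GCLM, a subunit of the rate-limiting enzyme of glutathione synthesis (-0.91 ± 0.19, 0 of 6). Each had an adjusted p of 0.156 in limma, which called 0 genes, with 1450 at an unadjusted p under 0.05. That fit used 1 shared spread for all etiologies. Fitted alone, acute infarction pairs gave 602 such genes, ischemic pairs 459 and nonischemic pairs 747. The counts of the shared fit therefore do not rank the etiologies. Camera placed 16 lists past the threshold, 11 higher and 5 lower, and 0 with an estimated correlation (lowest adjusted p = 0.542 with an estimated correlation). Without pair 7 the fit called 327 genes, 143 higher and 184 lower.

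In the 8 nonischemic pairs metallothioneins were higher at explant in 8 of 8 pairs, with a mean of 0.97 ± 0.61 (SD, n = 8; exact p = 0.00781, the smallest that 8 pairs can give, and 0.367 adjusted over 47 lists). BCL6, a transcriptional repressor, had a change of 0.99 ± 0.18 (8 of 8 pairs), the galactosyltransferase gene B4GALT4 of 0.82 ± 0.16 (8 of 8) and NFIL3 of 0.77 ± 0.17 (7 of 8). Oxidative phosphorylation had a mean of -0.23 ± 0.29 (higher in 2 of 8 pairs; exact p = 0.0781), the cardiac transcription factors -0.25 ± 0.16 (1 of 8; exact p = 0.0156), acute phase and inflammatory genes 0.41 ± 0.56 (6 of 8; exact p = 0.0938) and immediate early genes 0.61 ± 0.90 (5 of 8; exact p = 0.117). In the same pairs macrophage markers had a mean of 0.40 ± 0.98 (5 of 8; exact p = 0.305; 0.16 without pair 22 and 0.62 without pair 9), adipocyte markers 0.61 ± 1.09 (5 of 8; exact p = 0.164) and fibroblast markers 0.31 ± 0.92 (5 of 8; exact p = 0.359), and the mean changes of the RNA ratios given below were above 0. BCL6 and B4GALT4 had an adjusted p of 0.204 and NFIL3 of 0.509 in limma, which called 0 genes, with 546 at an unadjusted p under 0.05. Camera placed 12 lists past the threshold, 9 higher and 3 lower, and 0 with an estimated correlation (adjusted p = 0.118 for metallothioneins with an estimated correlation). Array weights gave 19 calls, and omission of acute infarction pairs 1 and 3 from the shared fit gave 3: BCL6, B4GALT4 and, lower, the glycogen-targeting phosphatase subunit PPP1R3C (-1.54).

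**Figure D3:**
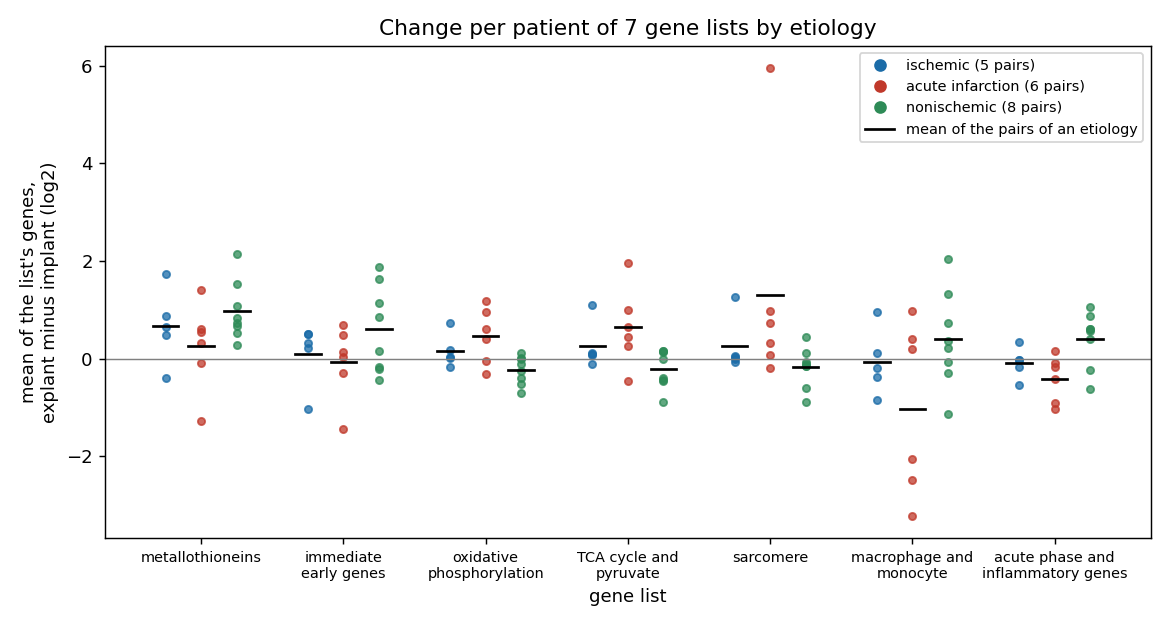
The y axis gives the mean change of the measured genes of a list, explant minus implant in log2, with 1 point per patient for the 7 lists on the x axis, coloured by etiology, and black bars for the mean of an etiology. Metallothioneins lie above 0 in 8 of 8 nonischemic pairs, and 1 acute infarction pair has a sarcomere change of 5.95.

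Whether the change at explant differed between etiologies was tested directly. CST7, an inhibitor of lysosomal cysteine proteases in immune cells, had a change of 0.73 ± 0.17 in acute infarction, -0.33 ± 0.19 in ischemic and -0.40 ± 0.15 in nonischemic pairs. LSM3, an RNA splicing factor, had 0.20 ± 0.13, 0.28 ± 0.14 and -0.48 ± 0.11, and the phospholipid acyltransferase MBOAT7 -0.91 ± 0.22, 0.02 ± 0.24 and 0.48 ± 0.19 in the same order. Each had an adjusted p of 0.525. The moderated F-test of limma called 0 genes, with 773 at an unadjusted p under 0.05, and the 3 pairwise contrasts called 0 as well, with 1399 for acute infarction against nonischemic, 335 for acute infarction against ischemic and 302 for ischemic against nonischemic. Across genes, which are not independent replicates, the changes of acute infarction correlated with those of ischemic pairs (Pearson's r = 0.335) and inversely with those of nonischemic pairs (r = -0.247). Among the lists, permutation of etiologies placed 0 past the threshold after adjustment (smallest adjusted p = 0.305), with 6 at an unadjusted p under 0.05, among them oxidative phosphorylation (permutation p = 0.0193), the TCA cycle list (permutation p = 0.0330) and acute phase genes (permutation p = 0.0210).

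At implant, tissue from acute infarction was set against the other etiologies. CCL2, the chemokine that attracts monocytes, was 8.53 ± 1.27 (SD, n = 6) in acute infarction, 6.11 ± 1.51 (n = 5) in ischemic and 6.77 ± 0.98 (n = 8) in nonischemic tissue. POLD4, a subunit of DNA polymerase delta, was 6.84 ± 0.49, 5.52 ± 0.49 and 5.57 ± 0.51, and the purine synthesis enzyme ATIC 8.15 ± 0.17, 7.97 ± 0.16 and 7.53 ± 0.23. The hypoxia response list had a level of 8.21 ± 0.23 in acute infarction, 7.97 ± 0.18 in ischemic and 7.94 ± 0.13 in nonischemic tissue (permutation p = 0.0305). None of these differences passed: the F-test of limma called 0 genes (smallest adjusted p 0.888), with 359 at an unadjusted p under 0.05. Permutation placed 0 lists past the threshold (smallest adjusted p = 0.873), with 2 at an unadjusted p under 0.05. Camera placed 19 lists past it for acute infarction against nonischemic, 11 for acute infarction against ischemic and 7 for ischemic against nonischemic, with 0 in each with an estimated correlation (lowest adjusted p = 0.552 with an estimated correlation). The ACTB 3' over 5' ratio at implant was 0.72 ± 0.46 in acute infarction, 0.24 ± 0.40 in ischemic and 0.01 ± 0.38 in nonischemic tissue, and the GAPDH ratio 0.23 ± 0.43, 0.20 ± 0.41 and -0.07 ± 0.11. The acute infarction array of pair 3 is among these implant arrays; without pairs 1 and 3, MYH6, the fast alpha myosin heavy chain, was called for acute infarction against ischemic tissue (2.80 higher, adjusted p = 0.0348).

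At explant, list means of energy metabolism genes were lowest in nonischemic tissue, by differences that did not pass the threshold after adjustment. The TCA cycle list was 9.08 ± 0.32 (SD, n = 8) in nonischemic, 9.52 ± 0.06 (n = 5) in ischemic and 9.50 ± 0.22 (n = 6) in acute infarction tissue (permutation p = 0.00737). Oxidative phosphorylation was 9.93 ± 0.28, 10.3 ± 0.09 and 10.3 ± 0.13 (permutation p = 0.00843), and cardiomyocyte markers were 11.4 ± 0.27, 11.7 ± 0.02 and 11.8 ± 0.15 (permutation p = 0.0116). ATP5F1C, a subunit of ATP synthase, was 11.2 ± 0.28 in nonischemic, 11.7 ± 0.19 in ischemic and 11.8 ± 0.13 in acute infarction tissue. UQCR11, of respiratory complex III, was 10.2 ± 0.25, 10.7 ± 0.21 and 10.7 ± 0.11. STX1A, a syntaxin of vesicle fusion, was 6.22 ± 0.52, 5.62 ± 0.48 and 4.97 ± 0.24. Permutation placed 0 lists past the threshold after adjustment (smallest adjusted p = 0.142), with 10 at an unadjusted p under 0.05. The F-test of limma called 0 genes (smallest adjusted p 0.637), with 539 at an unadjusted p under 0.05. Camera placed 21 lists past it for acute infarction against nonischemic and 17 for ischemic against nonischemic, and 0 with an estimated correlation (lowest adjusted p = 0.167 and 0.195 with an estimated correlation). With array weights STX1A was called for acute infarction against nonischemic (-1.26, adjusted p = 0.0364). Macrophage markers were 7.69 ± 0.73 in nonischemic, 6.97 ± 0.58 in ischemic and 7.10 ± 0.74 in acute infarction tissue at the same time. The ACTB 3' over 5' ratio at explant was 0.37 ± 0.55 in nonischemic, 0.16 ± 0.44 in ischemic and 0.05 ± 0.50 in acute infarction tissue. Nonischemic explants 2 and 8 had the lowest correlations of their group (0.802 and 0.817) and ACTB ratios of 1.07 and 1.19; without them, an omission chosen after seeing the data, the nonischemic level was 9.23 ± 0.20 (n = 6) for the TCA cycle, 10.0 ± 0.22 for oxidative phosphorylation and 11.6 ± 0.16 for cardiomyocyte markers.

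RNA integrity was compared because 3' over 5' ratios rise as RNA degrades. The log2 GAPDH ratio changed by -0.04 ± 0.32 (SD, n = 19) from implant to explant (permutation p = 0.577) and the ACTB ratio by -0.08 ± 0.73 (permutation p = 0.645). The ACTB change was -0.67 ± 0.58 in acute infarction (n = 6; exact p = 0.0625), -0.07 ± 0.70 in ischemic (n = 5; exact p = 0.875) and 0.36 ± 0.57 in nonischemic pairs (n = 8; exact p = 0.117). The 3' over middle ratios of nonischemic pairs changed by 0.09 ± 0.09 for GAPDH (higher in 7 of 8 pairs; exact p = 0.0313) and 0.27 ± 0.30 for ACTB (6 of 8; exact p = 0.0391), both unadjusted and in the direction of poorer RNA at explant, and those of acute infarction pairs by -0.19 ± 0.16 and -0.41 ± 0.48 (exact p = 0.0625 for each). Permutation of etiologies gave an adjusted p of 0.0449 for the ACTB change and 0.227 for the GAPDH change, over 5 measures. Lower ACTB ratios in acute infarction pairs and higher ones in nonischemic pairs ran beside the oxidative phosphorylation means of 0.47 and -0.23.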

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

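The tests on the acute infarction array of pair 3 were chosen or reworded after its values were seen, and the opposite directions of the respiratory chain genes were noticed in the data before they were tested. Tests of array brightness as an explanation were dropped after their results were seen, neither of which favoured it; with brightness as a covariate the median of the 10 called rises was 0.77 in place of 0.76.

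The implant array of acute infarction pair 3 had a mean correlation of 0.565 with the other arrays, against 0.845 to 0.888 in the rest of its group, and a cardiomyocyte marker mean of 5.48 against 10.9 to 11.8. A loss of cardiomyocytes alone is argued against by the fibroblast marker mean of 5.84, below the 7.64 to 9.90 of the other 37 arrays, since such a loss would raise the share of every other cell type; an earlier wording that asked only for a low cardiomyocyte mean was met. A sample mostly of macrophages and neutrophils remains a candidate explanation: the macrophage mean was 10.3 against at most 9.10 elsewhere (21 markers, 5 of them in another list), the neutrophil mean 10.0 against at most 9.79, and SPP1, a secreted protein of activated macrophages, was 12.01 against at most 11.2. RNA degradation cannot be told apart, because only 1 array had higher GAPDH and ACTB ratios, and that array correlated at 0.864 with the others. Whether the material was infarcted muscle, which the etiology allows, or came from elsewhere was not tested.

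Changes of most RNA ratios differed between etiologies, with an adjusted permutation p of 0.0449 for ACTB 3' over 5', 0.0449 for GAPDH 3' over middle and 0.0449 for ACTB 3' over middle. The GAPDH 3' over 5' ratio did not pass (adjusted permutation p = 0.227). Beside them, the mean change of the 67 oxidative phosphorylation genes was 0.70 ± 0.22 (SE) higher in the 6 acute infarction than in the 8 nonischemic pairs (exact p = 0.0110). Omission of acute infarction pairs 1 and 3 left 0.567 of this gap (0.40, exact p = 0.0848), which does not decide whether those arrays made it. Removing the trend within etiologies on the RNA ratios left 0.458 of the gap (0.32 ± 0.24), so RNA degradation is a candidate explanation. Removing that on the cardiomyocyte and macrophage markers left 0.404 (0.28 ± 0.16). Acute infarction pair 3, with a cardiomyocyte marker change of 6.16 against at most 1.30 in any other pair, weighs heavily in that trend. A change in cell composition thus stays a candidate, on which this removal cannot decide for the other pairs. A difference between the etiologies themselves stays open and untested apart from these.

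Other arrays and pairs lay far from the rest of their group by Dixon's test, which picked 20 values from 123 groups where chance alone picks about 5 percent. The deposited median intensity of nonischemic explant 22 was 93.4, against 24.3 to 54.7 in its group. The explant array of acute infarction 1 had a mean correlation of 0.796 (others 0.874 to 0.904) and that of ischemic 4 had 0.873 (others 0.893 to 0.897). The GAPDH ratio was 0.58 in ischemic explant 4 and 0.59 in nonischemic explant 7, and the ACTB ratio was 1.04 in acute infarction explant 7, each the highest of its group. The implant array of ischemic 13 had a cardiomyocyte marker mean of 10.4, against 11.6 to 11.8. Ischemic pair 13 had list changes of 1.26 for sarcomere, 1.30 for cardiomyocyte markers, 1.10 for the TCA cycle, 0.54 for fatty acid genes and -1.03 for immediate early genes. Acute infarction pair 3 had changes of 5.95 for sarcomere, 6.16 for cardiomyocyte markers, 2.28 for calcium handling and 3.27 for smooth muscle markers. The interferon response changed by -0.77 in nonischemic pair 9 and growth and IGF signalling by -0.44 in nonischemic pair 2, where the other nonischemic pairs lay between 0.07 and 0.39.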

How the results depend on the processing

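Omission of the 2 acute infarction pairs, the brightness and cardiomyocyte covariates, the sign flips of list changes, the scalings of the lists and the omission of each pair between etiologies and for list means, and of 2 nonischemic explants, were alternatives chosen after seeing the data; the cause of a changed value was not tested unless stated. The count of called genes over all pairs (12) was 1 without the filter and 1 with every probe set tested (both NRP1; more tests are adjusted for), 0 for values as deposited, 5 after median centring, 141 with array weights, 19 without acute infarction pairs 1 and 3 (10 of the 12 among them), and 1 (NRP1) with the GAPDH ratio as a covariate. On the pairing, the count was 2 with no patient block and 19 with the patient as a random block (10 of the 12); no block left the count of every etiology at 0 and that of lists at 15, 14 of them the same. Other filters, pseudocounts, probe set rules, plain eBayes and the brightness and cardiomyocyte covariates gave 8 to 15 calls. Leaving out 1 pair gave 0 to 33: 0 without acute infarction 5 or 7, ischemic 4 or 13 or nonischemic 3, 4, 6 or 9; 1 without ischemic 8 or 12 or nonischemic 22; 2 without acute infarction 3 or 6 or ischemic 7; 5 without nonischemic 7; 21 without nonischemic 8; and 33 without nonischemic 2. In these settings apart from single omissions the called genes kept direction and threshold in 118 values, lost the threshold in 79 and reversed in 0, and NRP1 passed in 15 of 17. Genes named without a call stayed so in 1359 values and passed in 4 (GATA4 in 2, SPRY1 and CEBPB in 1 each). Ischemic calls (0) became 1 with array weights and 3 in a fit of that etiology alone; nonischemic calls (0) became 19 with array weights and 3 without acute infarction pairs 1 and 3. Acute infarction calls ranged from 0 to 327 on leaving out 1 of its pairs, 327 without pair 7. Differences between etiologies in change and at implant gave 0 throughout, and explant gave 1 without the filter (ZNF407); their pairwise contrasts stayed at 0 in 105 values and gave 1 call in 3 (ZNF407 and STX1A at explant, MYH6 at implant). Genes named per etiology or by an F-test between etiologies stayed uncalled in 209 values and passed in 7. In 7 more values they moved by over their SD across pairs, among them PTN (0.11 without cross-hybridizing probe sets). Their direction was not counted. Lists past the threshold (15) were 0 with an estimated correlation, 0 with fry, 0 by sign flips, 5 without acute infarction pairs 1 and 3, 19 as deposited and 14 after median centring. Without those pairs the oxidative phosphorylation list turned lower (adjusted p 0.586) and the ACTB ratio change was 0.0160 in place of -0.0781. As deposited, the median change of all genes was -0.06, with 0.10 in ischemic, -0.10 in acute infarction and -0.12 in nonischemic pairs. Signal over background limits dim genes: FKBP5 (6.23) and ATAD2 (5.95) lie near the filter at 5.56, and their changes are understated most by the pseudocount.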

Other observations

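Several genes of lists that camera did not call rose adjusted over the list alone; they were picked after their values were seen, and none passed over all genes. Among 25 hypoxia response genes DDIT4, a stress-induced inhibitor of mTOR signalling, rose by 0.99 ± 0.23 (SE, n = 19; higher in 15 of 19 pairs), EPAS1, a hypoxia-inducible factor, by 0.30 ± 0.10 and the oxygen sensor EGLN1 by 0.25 ± 0.08, while LDHA, lactate dehydrogenase, had -0.27 ± 0.10 and did not pass. NFKBIA, which holds NF-kappa-B in the cytoplasm, rose by 0.61 ± 0.16 in 16 pairs, and the potassium channel KCNK1 by 0.59 ± 0.14 in 16. PYGM, the muscle glycogen phosphorylase, rose by 0.58 ± 0.16 in 17 of 19 pairs and ALDOC, an aldolase, by 0.45 ± 0.13. With limma adjusted over the list alone, p was 0.00731 for DDIT4, 0.0264 for NFKBIA, 0.00522 for KCNK1 and 0.0352 for PYGM.

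Of the natriuretic peptides and fetal-type genes, CORIN, the protease that activates natriuretic peptides, rose by 0.88 ± 0.26 and the atrial myosin light chain MYL7 by 1.17 ± 0.36, each with an adjusted p of 0.0281 adjusted over the list alone (limma). The mean change of the list was 0.14, with 3.77 in acute infarction pair 3 and at most 1.04 in any other pair. Without acute infarction pairs 1 and 3 it was -0.06 ± 0.12 (n = 17). In the same list NPPA, the precursor of atrial natriuretic peptide, had a change of -1.06 ± 0.41 and was higher at explant in 5 of 19 pairs (adjusted p = 0.489) and did not pass over the list alone. In 4 other lists AGTR1, the angiotensin receptor, rose by 0.70 ± 0.22 (adjusted p = 0.0463 over its list), BMP2 by 0.37 ± 0.11 and SMAD4 by 0.26 ± 0.08. The haemoglobin chain HBD fell by 0.58 ± 0.19 (adjusted p = 0.0265 over its list) and the autophagy gene ATG3 by 0.26 ± 0.08, while the other 2 members of the autophagy and lysosome list past the threshold over that list, FOXO3 and FOXO1, rose.

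The explanations of the 10 called rises were tested after those genes had been seen; FKBP5, PDK4, KLF9, TXNIP and NFIL3 are known to be induced by glucocorticoids, and a list of 25 other induced genes was written after the 60 smallest p-values were seen and before its own test. Its 16 measured genes, 6 of them in another list, had a mean change of 0.159 (95 percent bootstrap interval 0.0348 to 0.280; permutation p = 0.0230; higher in 13 of 19 pairs), with GLUL at 0.37 ± 0.14, LPIN1 at 0.31 ± 0.10 and 0 past the threshold adjusted over the list alone (limma; 3 at an unadjusted p under 0.05). For RNA degradation, the median rise kept 0.960 of its size with the GAPDH ratio as a covariate (0.76 to 0.73, median SE 0.147 in both). That ratio changed by a mean of only -0.04 over the 19 pairs, so the covariate could hardly move the rises. The result shows that a mean shift of this ratio did not carry them. It cannot decide on RNA degradation that this ratio misses. All 10 calls ended, as the limma adjusted p went from 0.0425 to 0.0457 without the covariate to 0.0635 to 0.0823 with it. The smaller change, the lost degree of freedom and the joint adjustment were not told apart. For a larger share of cardiomyocytes, 0.853 remained with their markers as a covariate (0.76 to 0.65) and 5 rises were still called. These markers changed by 6.16 in acute infarction pair 3 and by at most 1.30 in any other pair. That pair largely sets the covariate, so the test cannot decide on a share of cardiomyocytes in the other pairs. Given the mean of 0.159 for the list of induced genes, a glucocorticoid response at explant may contribute, as a hypothesis found and tested on the same data. It leaves open that this list mean was -0.02 in acute infarction pairs, where FKBP5 changed by 1.38 ± 0.61. Treatment, fasting and time of day were not tested.

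Sign flips that reversed implant and explant in whole pairs, and reassignments of etiologies among patients, show how large the counts become by chance. A count of 12 called genes was reached by 1 of 100 sign flips, the real one, and the highest other gave 3. Chance is thus an unlikely source of that count under the main processing. The flips do not test any single gene of the 12. The count was over 0 in 11 of 19 omissions of 1 pair and 0 for values as deposited. Without acute infarction pair 3 the 2 called genes were both lower. No rise was called either without acute infarction 6, ischemic 8 or 12 or nonischemic 22, where every called gene was lower. The same held without the filter, with every probe set tested and with the GAPDH ratio as a covariate. The 610 genes at an unadjusted p under 0.05 were reached by 16 of 100 (highest other 1615), so chance cannot be excluded for that count, nor for the 15 lists called by camera, reached by 45 of 100 (highest other 28). In acute infarction 5 of 32 flips reached the 1450 genes (highest other 2069) and in nonischemic pairs 7 of 100 reached 546 (highest other 833), so chance cannot be excluded. The 16 flips of the ischemic pairs are too few for a share under 0.05 (real count 237, highest other 231). For the difference in change 8 of 100 reassignments reached 773 genes (highest other 1607), for implant 40 of 100 reached 359 (highest other 1369) and for explant 25 of 100 reached 539 (highest other 1555), so chance cannot be excluded for these either. Splits with several times the real count, as at implant, may point to a structure of the samples other than their labels or to genes that move together, and neither was tested.

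Among 3150 probe sets with several symbols or none, limma called 0 over all pairs (smallest adjusted p 0.0905), with 162 at an unadjusted p under 0.05, and 0 of the 68 Affymetrix controls passed.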
